A study of Mus musculus with 4 samples.

How the data were processed

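Gene expression was measured in single living CD4 T cells (CD45+CD3+CD4+, 7AAD negative by flow sorting) of the small intestine lamina propria of wild-type C57Bl/6 mice, per the labels' protocols. Peyer's patches had been removed and the tissue digested with collagenase. The series holds 4 libraries made with the Chromium 5′ chemistry, all of 1 group. The labels do not state that each library held the cells of exactly 1 mouse, so replicates are called libraries here. No treatment, genotype or time point was compared, and no T cell receptor library was analysed here.

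The authors deposited 1 matrix of UMI counts per library, made with Cell Ranger 3.0.2 against mm10, per the submitters' processing notes. Every deposited value was a whole count, and the matrices held 31053 gene IDs, of which 31011 matched the GENCODE mm10 annotation used for positions. Gene IDs that share a symbol with another (71 gene IDs) were kept apart by their ID. The matrices held 5763, 6013, 5669 and 5459 barcodes in libraries 1 to 4, with 28783972, 26407082, 23918884 and 26681150 UMIs in total. Since the lowest barcode held 502 UMIs, a filter had been applied to barcodes before the counts were deposited by the authors, and empty droplets could not be used to measure free RNA.

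Everything that follows was computed from those counts. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 22534 of 22904. Doublet scores came from Scrublet (scanpy 1.11.5) in each library, and the highest-scoring cells were removed at a rate of 0.8% per 1000 barcodes, 1033 cells in all, which left 21501. Counts were scaled to 10000 UMIs per cell and log-transformed. Clustering used the 101 marker genes fixed beforehand and the 1000 most variable genes. The variable genes left out the genes of the readout lists (224, but not Aldoa, whose symbol more than 1 gene ID shares), T cell receptor and immunoglobulin genes, ribosomal protein genes and mitochondrial genes. By contrast, the markers included Trdc, Trdv4, Tcrg-C1, Tcrg-C2, Igha, Igkc and Jchain. No gene that defined a cluster was tested. On the 1032 features this gave, 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.0 were used, and Treg-like cells were clustered again at resolution 0.5 on 1043 features.

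A cluster took the name of the marker list with the highest mean log2 fold over the other clusters, where that mean was at least 0.75 and at least 3 markers were at 1.5-fold or more. The lists named Treg, Th17, Th1, Th2, Tfh, naive or central memory, cytotoxic, cycling, interferon-response, innate-like T, gamma-delta T, B cell, plasma cell, myeloid, epithelial, stromal or endothelial, mast cell and erythroid cells. A cluster led by DNA replication genes was set aside with the cycling cells. Cells are called Treg-like or Th17-like because transcripts alone named them.

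UMIs were summed per library and class, so that libraries and not cells were the replicates. edgeR 4.0.16 quasi-likelihood tests (glmQLFit and glmQLFTest, TMM scaling, filterByExpr, library as a block) were adjusted by Benjamini-Hochberg at 0.05 over the genes tested, which never included clustering features. Treg-like cells were compared with all other αβ CD4 T cells in 1 fit with 3 residual degrees of freedom. Th17-like and Th1-like sums went into another fit with 9 residual degrees of freedom, together with 2 sets of Treg-like sums. Comparisons of those sets, planned before the data were examined, and 1 gene's detection are not reported here. Shares of cells are means and SD over 4 libraries with no test, as there was 1 group. For detection of Foxp3, Ikzf2 and Gata3, each cell was thinned to 2000 UMIs and shallower cells were left out.

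Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The 17 readout lists, written before the data were examined, covered suppressive mediators, co-inhibitory receptors, co-stimulatory receptors, chemokine and migratory receptors, integrins, cytokine receptors, effector cytokines, TCR-induced genes, tissue-dissociation stress, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, ligand-sensing nuclear receptors with AhR, T cell transcription factors, cytokine feedback and survival, interferon-gamma GTPases, and granzymes and killing. Ribosomal protein genes made a further list. Named genes were the 10 highest and 10 lowest log2 fold changes among genes past the threshold that changed in the same direction in all 4 libraries, with a mean of at least 20 CPM (UMIs scaled to a common sum of 1e6) in 1 class, leaving out predicted genes, receptor, ribosomal and mitochondrial genes. Up to 4 members of each list with the smallest adjusted p were named as well.

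The markers, lists, filters, comparisons, naming rule for genes and most alternatives were fixed before the data were examined. Chosen after the data were seen were the thresholds that name a cluster, the replication rule, the removal of a pruning step in the neighbour graph, the definition of a mixed Treg-like sub-cluster (median UMIs over 1.5 times the Treg-like median, with Ifng over 2-fold), the split of the other sub-clusters into Gata3-high and Gata3-low by Gata3 and Klrg1, and the whole comparison of Gata3-high with Gata3-low cells, fitted with Th17-like and Th1-like sums.

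The tests were tried on simulated counts with 200 changed genes at a dispersion of 0.02. The fits to the real sums had lower common dispersions, 0.00291, 0.00471 and 0.00403 in the order given next, and called far more genes. No library effect was simulated. The simulated values therefore do not give the recovery or the false calls of the real fits. With 10030 genes, the fit of Treg-like against other cells recovered 40% of genes changed 1.5-fold, 84.1% of those changed 2-fold and 98.5% of those changed 4-fold. For Th17-like against Th1-like cells, with 6635 genes, they were 47%, 80% and 100%, and for Gata3-high against Gata3-low cells, with 7069 genes, 26.6%, 70.1% and 98.4%. False calls made up 4.67%, 3.9% and 4.51% of the calls in these 3 simulations, in that order.

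Alternatives tried were DESeq2 1.42.0, library size without TMM, no filter on low counts, no library block, leaving out each library, no doublet removal, at most 5% mitochondrial UMIs, lower (0.7) and higher (1.4) clustering resolution, clustering on library-centred values, classes gated on UMIs instead of clusters, cycling cells assigned by Foxp3, only the classes compared in a fit, detection without thinning or at 2 UMIs or more, and an estimated correlation for lists. Leaving out the mixed sub-cluster, and for Treg-like against other cells the 3 clusters named next, was added after the data were seen. Cycling, myeloid and plasma cells were in neither class of a comparison, whereas all remaining cells counted as other αβ CD4 T cells. These included 29 innate-like T cells, the 2074 cells of the cluster led by Cd8a and γ-chain receptor genes, and 254 cells of a low-UMI cluster led by Fabp6 and Apoa1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.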

Results

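Transcripts were counted in single CD4 T cells of the small intestine lamina propria, the connective tissue under the gut epithelium, of wild-type C57Bl/6 mice. The 4 libraries formed 1 group, so cell classes were compared with each other within the same libraries, not mice with mice. The question, from the labels and the series title, was how regulatory T (Treg) cells of this tissue differ from other CD4 T cells and among themselves. Libraries 1 to 4 held 28783972, 26407082, 23918884 and 26681150 UMIs, and the 5402, 5626, 5324 and 5149 cells analysed had median depths of 4177, 3629, 3647 and 3995 UMIs.

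Treg-like cells, named by Foxp3 (the lineage factor of Treg cells) and its companions, made up 7.94% ± 1.64 (SD, n = 4 libraries) of the cells, between 5.69% and 9.60%. Their Foxp3 level was 361 ± 62.1 CPM, against 5.34 ± 0.657 CPM in all other αβ CD4 T cells. Th1-like cells made up 15.4% ± 2.13, with 953 ± 185 CPM of Ifng, the cytokine that activates macrophages, and 951 ± 49.0 CPM of the IL-12 receptor chain Il12rb2. Other Th1 markers set the class apart less. Against all αβ CD4 T cells outside the Treg-like class, Th1-like cells included, Tbx21 stood at 110 ± 10.8 against 89.2 ± 8.09 CPM. Cxcr3 stood at 262.5 ± 20.4 against 242 ± 24.4 CPM, and Nkg7 at 1517 ± 223 against 1073 ± 130 CPM. Ccl5 was lower, at 2544 ± 309 against 3965 ± 839 CPM. Th17-like cells made up 2.92% ± 1.09 and carried 1037 ± 482 CPM of Il17a and 793 ± 367 CPM of Il22, cytokines that act on the epithelial barrier. Cytotoxic cells made up 13.1% ± 2.36, in a cluster of 2074 cells led by Cd8a and γ-chain receptor genes and another of 735 led by Gzma and Ccl5, and smaller classes were interferon-response cells (3.13% ± 1.25), naive or central memory-like cells (1.42% ± 0.717), Tfh-like cells (1.03% to 2.26% over the libraries) and Th2-like cells (0.666% to 0.764% in libraries 1 to 3 and 2.51% in library 4; mean 1.16%, or 0.715% without library 4).

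Cycling or replicating cells made up 5.04% ± 0.816, and 47.4% ± 1.82 of cells lay in clusters that no marker list named. Cells named as other types were few: 0.871% myeloid, 0.134% ± 0.0435 innate-like T and 0.120% ± 0.0661 plasma cells. The gamma-delta T, epithelial, stromal or endothelial, mast cell and erythroid lists had 2, 2, 1, 1 and 0 markers detected, too few for the rule to name a cluster. Their other markers stayed under 20 CPM in every cluster, which argues against whole clusters of stromal, mast or erythroid cells. Epithelial and gamma-delta T cells, and scattered cells of the other kinds, were not ruled out. The 2 gamma-delta markers detected were the γ-chain genes Tcrg-C1 and Tcrg-C2. They had a higher mean log2 fold than the list that named the cluster in the larger cytotoxic cluster (1.53 against 1.19) and in a Th1-like cluster (1.16 against 1.08). The δ-chain genes Trdc and Trdv4 were those under 20 CPM in every cluster, so the higher fold rested on γ-chain genes alone. In Th1-like cells Tcrg-C2 stood at 77.2 ± 25.2 CPM and Trdc at 2.06 ± 1.94 CPM. Some shares depended strongly on the settings. Th17-like cells made up 6.79% at a mitochondrial share of at most 5% and 14.2% with UMI gates, Th1-like cells 32.8% with UMI gates, and cytotoxic cells 6.76% without doublet removal. Unnamed cells ranged from 42.5% to 51.6%, whereas the Treg-like share moved by less than 1 SD under all settings that were run.

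**Figure D1:**
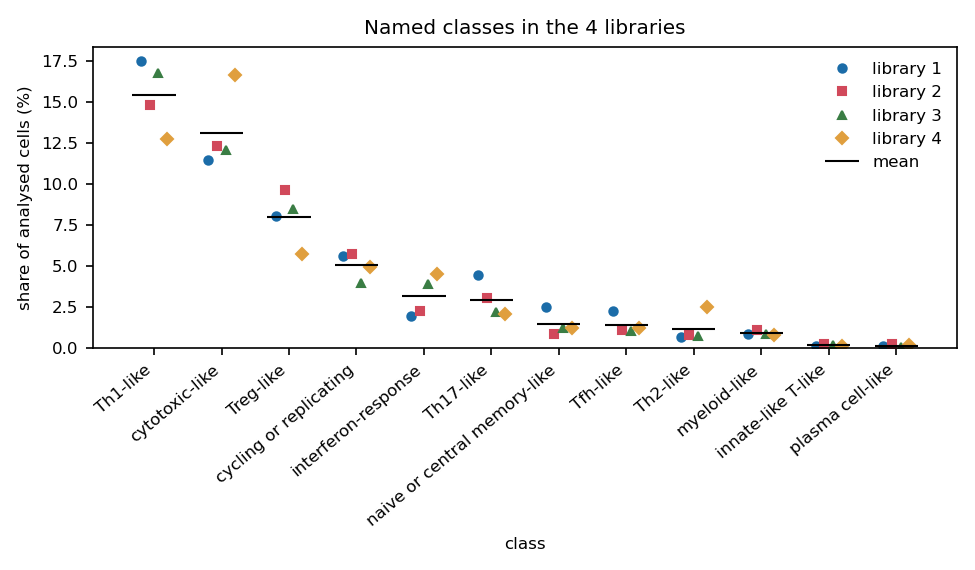
Share of analysed cells in each class, in percent, with 1 point per library (n = 4) and a line at the mean. Treg-like cells lie between 5.69% and 9.60% in the 4 libraries.

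Within Treg-like cells, Gata3, a factor of type 2 and tissue Treg cells, and Klrg1, an inhibitory receptor of effector cells, separated most sub-clusters. Gata3-high cells were 55.0% ± 7.11 of Treg-like cells (952 cells; Gata3 781 ± 96.2 CPM, Klrg1 1167 ± 155 CPM). Gata3-low cells were 37.6% ± 8.88 (637 cells; Gata3 164 ± 48.6 CPM, Klrg1 269 ± 54.2 CPM). A mixed sub-cluster with Ifng and high UMI totals made up the other 7.47% ± 2.58 (126 cells). The sub-clusters were split by Gata3 and Klrg1 after the data were seen.

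At a common depth of 2000 UMIs, 49.2% ± 5.81 of Treg-like cells held a Foxp3 UMI (X, 7573644 to 7595245, mm10), 80.5% ± 3.62 a UMI of Ikzf2, which encodes Helios (chromosome 1, 69531214 to 69687245), and 50.7% ± 4.66 a Gata3 UMI (chromosome 2, 9857078 to 9890034). In Th1-like cells the shares were 0.454%, 24.2% and 11.6%, and in naive or central memory-like cells, the lowest class for Ikzf2 and Gata3, they were 2.17%, 1.35% and 5.66%. That 2.17% for Foxp3 came from library 2 alone (8.70%, with 0% in libraries 1, 3 and 4). Median depths before thinning were 4104, 3994 and 4266 UMIs, and 1666 of the 1715 Treg-like cells were deep enough. In Th17-like cells (median 5704.5 UMIs) 24.2% ± 5.70 held an Ikzf2 UMI.

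Ikzf2 and Gata3 were found together about as often as independent detection gives, in 39.98% ± 2.96 of Treg-like cells against 40.7%, and were above it in 1 of 4 libraries. Foxp3 and Gata3 together were found in 24.2% ± 0.820 against 24.8% ± 1.59. These shares depend on depth: without thinning the share with Foxp3 was 71.2%.

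**Figure D2:**
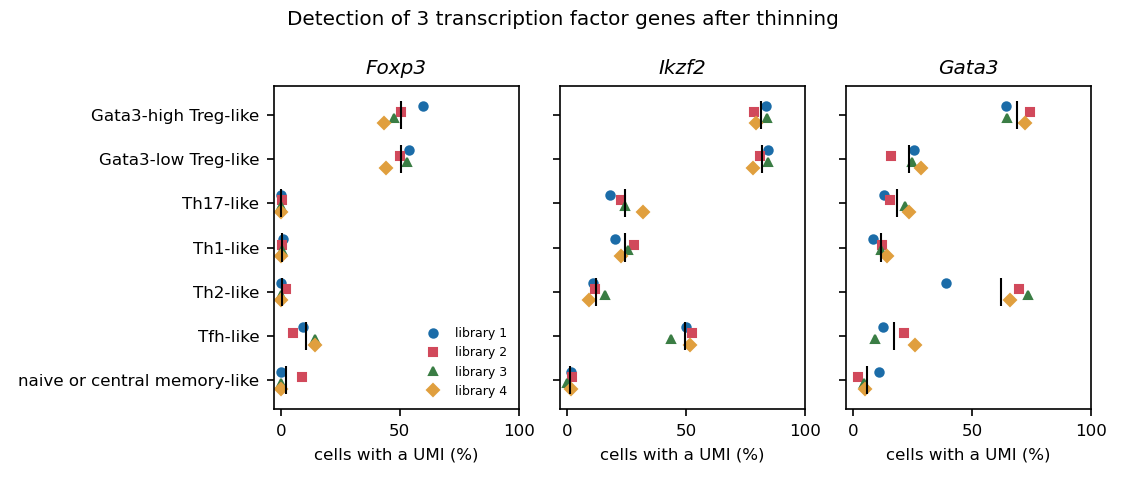
Percent of cells with at least 1 UMI of Foxp3, Ikzf2 and Gata3 after thinning to 2000 UMIs, in 7 classes, with 1 point per library and a vertical line at the mean. Ikzf2 stands at 81.4% in Gata3-high Treg-like, 82.1% in Gata3-low Treg-like and 24.2% in Th1-like cells, and Gata3 at 69.0%, 23.6% and 11.6%.

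All 12 suppressive mediators rose in Treg-like cells against all other αβ CD4 T cells (12 as well when adjusted over the list alone), with a median log2 fold change of 2.84. Limma camera gave this list an adjusted p of 1.0e-11, and an adjusted p = 0.0849 with an estimated correlation. Areg, which encodes amphiregulin, a growth factor for epithelium, stood at 2029 ± 252 CPM against 117 ± 38.4 CPM (log2 fold change 4.21 ± 0.11, SE). Penk, the gene of the enkephalin precursor, rose by 4.41 ± 0.07, to 734 ± 258 CPM, and Il10, an anti-inflammatory cytokine, by 3.59 ± 0.07, to 390 ± 58.8 CPM. Itgb8 and Lrrc32, whose products activate and dock latent TGF-β, rose by 4.70 ± 0.17 and 4.59 ± 0.20. Il2, the T cell growth factor, fell by 3.41 ± 0.18, from 60.6 ± 4.93 to 5.78 ± 4.10 CPM, and Cd40lg, which encodes the ligand through which T cells help B cells, fell by 2.40 ± 0.07.

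Of the 9 co-inhibitory receptors 6 rose and 2 fell, as over the list alone, among them Havcr2 (4.29 ± 0.24), Lag3 (2.93 ± 0.06) and Tigit (2.32 ± 0.05), which restrain T cell activation (camera adjusted p = 0.0498). That call was lost with an estimated correlation (adjusted p = 0.382) and without library 1, 2 or 4 (adjusted p = 0.0677, 0.0524 and 0.0755). Here too the estimate (-0.0792) lay under the preset 0.01. Of 26 T cell transcription factors 15 rose and 5 fell, the same over the list alone (camera adjusted p = 0.0042, 0.382 with an estimated correlation), led by Nfil3 (2.25 ± 0.09) and Tox (1.22 ± 0.06).

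Gene by gene, effector cytokines went mostly the other way: 8 of 13 fell and 2 rose (9 and 2 over the list alone). Xcl1, a chemokine for dendritic cells, fell by 3.41 ± 0.17 and Tnf by 1.59 ± 0.10. Th1 markers, used for clustering and so not tested, were lower in Treg-like cells too. Examples are Ifng (67.1 ± 21.0 against 333.5 ± 35.8 CPM), Il12rb2 (53.9 ± 16.6 against 243.5 ± 21.8 CPM) and Ccl5 (906 ± 84.7 against 3965 ± 839 CPM). As a list the effector cytokines did not pass camera (adjusted p = 0.0528), though they did without library 3 (0.0301) or library 4 (0.0181). The other 14 lists did not pass camera either. By fry, which asks only whether a list's genes move 1 way on balance and does not compare them with other genes, 11 of these 15 lists passed (adjusted p from 0.00336 to 0.0260). Those that did not were the TCR-induced, oxidative phosphorylation, interferon-gamma GTPase and ribosomal protein lists. Numbers that rose and fell, over all genes, were 6 and 2 of 10 co-stimulatory receptors, among which Tnfrsf9 (4-1BB) rose by 4.42 ± 0.08, 6 and 3 of 11 chemokine and migratory receptors, among which the gut homing receptor gene Gpr15 rose by 5.01 ± 0.25, 3 and 4 of 10 integrins, and 11 and 4 of 20 cytokine receptors. They were 5 and 5 of 12 TCR-induced genes, 3 and 5 of 14 tissue-dissociation stress genes, 6 and 2 of 14 glycolysis genes, 1 and 2 of 17 oxidative phosphorylation genes, and 1 and 9 of 13 genes of cholesterol and fatty acid synthesis. For 10 nuclear receptor and AhR genes they were 3 and 2, for 12 cytokine feedback and survival genes 8 and 4, for 9 interferon-gamma GTPases 1 and 3, for 5 granzyme and killing genes 1 and 3, and for 83 ribosomal protein genes 4 and 21. Over the lists alone these were the same apart from 5 falling cytokine receptors, 6 rising TCR-induced genes, 4 rising and 6 falling stress genes, 2 rising cholesterol genes and 19 falling ribosomal protein genes. Counts that another scaling moved by over 1.5 times and at least 2 genes were falling ribosomal protein genes (36 by library size alone), falling cholesterol genes (5 with DESeq2) and falling TCR-induced genes (3 with DESeq2). In the stress and interferon-gamma GTPase lists the median (0.06 and 0.03) and the direction of camera (down) differed in sign.

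Of 10167 genes tested by edgeR, 3715 passed Benjamini-Hochberg adjustment, 1976 higher and 1739 lower in Treg-like cells. Penk (ENSMUSG00000045573; chromosome 4, 4133531 to 4138819, mm10) had an adjusted p of 2.1e-20, Il10 2.5e-19 and Areg 1.9e-17, each higher in 4 of 4 libraries, and Il2 4.1e-12 and Cd40lg 4.2e-16, each lower in 4 of 4. The classes were drawn from the same cells that were tested, by genes that were not tested, so these p-values describe differences between clusters and not an independent sorting of Treg cells.

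**Figure D3:**
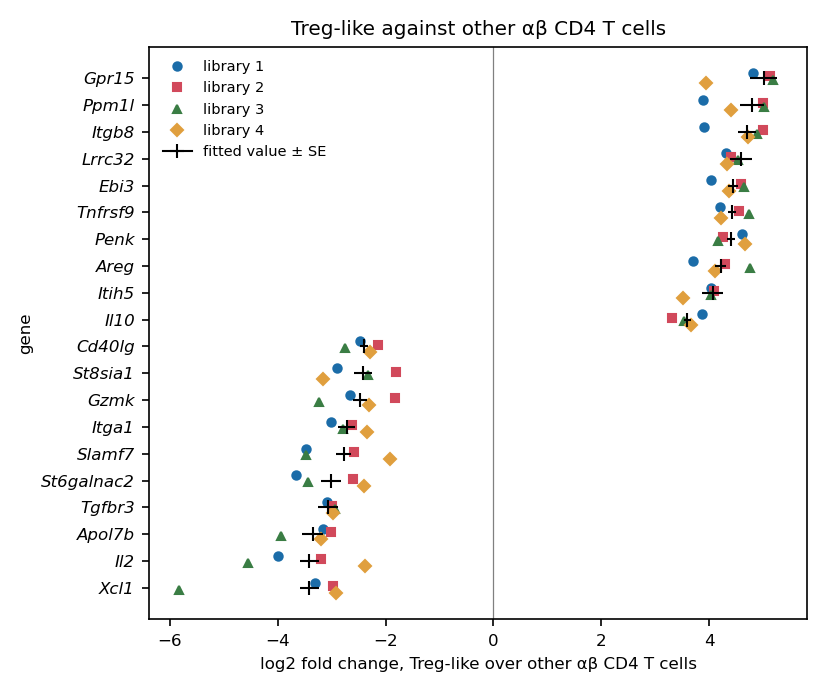
Log2 fold change of the 10 highest and 10 lowest named genes in Treg-like against all other αβ CD4 T cells, with 1 point per library and the fitted value ± SE. Gpr15 is at 5.01 and Penk at 4.41, Xcl1 at -3.41 and Cd40lg at -2.40, and every library lies on the same side of 0 for each gene shown.

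Th17-like cells, the barrier-protecting effector class, differed from Th1-like cells in cytokine receptors and killing genes (camera adjusted p = 1.7e-11 and 4.4e-07). The Th1-like class pooled clusters of 1695 and 1625 cells, in a mix that changed by library. The larger was 12.3%, 8.37%, 6.33% and 4.31% of libraries 1 to 4, the smaller 5.15%, 6.43%, 10.4% and 8.39%. Il9r, the IL-9 receptor gene, rose by a log2 fold change of 4.10 ± 0.28, to 40.7 ± 5.40 CPM against 2.34 ± 1.28 CPM, Slamf6, a co-receptor of activation, by 2.72 ± 0.12, and Ccr4, a chemokine receptor gene, by 2.39 ± 0.14. In the other direction Ccl4, a chemokine gene of activated T cells, fell by 6.44 ± 0.30, to 1.95 ± 0.739 CPM against 205 ± 93.7 CPM. Gzmb fell by 3.49 ± 0.20 and Prf1, the pore-forming perforin gene, by 4.43 ± 0.34. Il10 fell by 5.03 ± 0.37, from 139 ± 36.8 CPM in Th1-like cells. Markers of other classes, used for clustering and so not tested, were higher in Th17-like than in Th1-like cells. They were, of naive or central memory cells, Ccr7 (53.5 ± 14.6 against 1.14 ± 0.984 CPM), S1pr1 (98.6 ± 14.96 against 3.69 ± 1.21 CPM) and Klf2 (174 ± 30.3 against 18.4 ± 7.03 CPM). Of cycling cells they were Stmn1 (27.3 ± 8.63 against 3.95 ± 1.69 CPM), Ube2c (12.3 ± 4.73 against 1.01 ± 0.505 CPM) and Birc5 (3.5 ± 1.92 against 0.262 ± 0.308 CPM). The cycling markers Mki67 (21.1 ± 8.47 against 17.9 ± 2.42 CPM), Top2a (29.1 ± 9.04 against 24.6 ± 6.92 CPM) and Cdk1 (2.21 ± 0.625 against 2.30 ± 0.792 CPM) were about alike.

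All 4 measured granzyme and killing genes fell (4 over the list alone; camera adjusted p = 4.4e-07, 0.00238 with an estimated correlation). Of 18 cytokine receptors 11 fell and 2 rose (14 and 2 over the list alone; adjusted p = 1.7e-11, 0.00238 with an estimated correlation), among them the receptor genes for IL-7, Il7r (-1.96 ± 0.11), and IL-18, Il18r1 (-1.91 ± 0.11). Of 12 cytokine feedback and survival genes 11 fell and 1 rose (the same over the list alone; 9.2e-06, 0.00351 with an estimated correlation). Of 8 nuclear receptor and AhR genes 5 fell and 1 rose (the same; 0.00102, 0.0313 with an estimated correlation), led by Ahrr, the repressor of AhR (-3.03 ± 0.28), and Tiparp, an AhR target (-1.24 ± 0.11). Energy genes rose: 8 of 13 for glycolysis with 1 lower (the same over the list alone; 0.000107, 0.00852 with an estimated correlation), such as Ldha (0.82 ± 0.07), and 12 of 17 for oxidative phosphorylation with 0 lower (the same; 1.7e-06, 0.00238 with an estimated correlation), such as Atp5a1 (0.55 ± 0.06). Th17-like cells also held more UMIs per cell (median 5704.5 against 3994), and a link of these lists to that difference was not tested.

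Calls for 7 further lists were lost with an estimated correlation. Lower in Th17-like cells were 5 of 9 interferon-gamma GTPases with 1 higher (the same over the list alone; adjusted p = 0.000278, 0.0615 with an estimated correlation). So were 6 of 11 TCR-induced genes with 1 higher (7 and 1; 0.00314, 0.139), 7 of 12 tissue-dissociation stress genes (8; 0.00334, 0.0734). Lower too were 7 of 13 cholesterol and fatty acid genes with 1 higher (9 and 1; 0.00955, 0.139), and 13 of 25 T cell transcription factors with 6 higher (the same; 0.0390, 0.162), the last of each pair being the adjusted p with an estimated correlation. Higher were 71 of 83 ribosomal protein genes (73; 9.8e-34, 0.0734) and 5 of 10 co-stimulatory receptors with 2 lower (the same; 0.00955, 0.0943), the latter not passing without library 4 (0.0625).

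The other 5 lists did not pass camera. Suppressive mediators, chemokine and migratory receptors and effector cytokines passed fry, each downward (adjusted p = 0.000181, 0.00406 and 0.0388). The cholesterol list passed camera but not fry (0.0579). Numbers higher and lower were 4 and 4 of 10 chemokine and migratory receptors (adjusted p = 0.144), 3 and 4 of 12 suppressive mediators (0.144), 3 and 3 of 9 co-inhibitory receptors (0.747), 2 and 2 of 10 integrins (0.707) and 4 and 5 of 11 effector cytokines (0.529). Over the lists alone these were the same apart from 5 higher effector cytokines. Under another scaling, higher effector cytokines numbered 2 (DESeq2) and lower ribosomal protein genes 2 (library size alone), and no other list count moved by over 1.5 times and at least 2 genes. In all 5 the median (0.21, 0.16, 0.28, -0.05 and 0.13, in that order) and the direction of camera differed in sign.

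Of 6756 genes tested by edgeR 2065 passed, 1082 higher and 983 lower in Th17-like cells. Ccl4 had an adjusted p of 1.7e-17, Gzmb 3.3e-15, Slamf6 2.9e-18 and Il9r 1.5e-13, each in the same direction in 4 of 4 libraries. These p-values too describe differences between clusters drawn from the same cells. With classes gated on UMIs instead of clusters, 892 genes passed, and Tigit (-0.81 ± 0.08 between clusters) stood at 0.02. By library size alone 37.5% of calls were higher, against 52.4% with TMM.

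Gata3-high and Gata3-low Treg-like cells, a comparison added after the data were seen, differed in killing genes as a list (camera adjusted p = 5.1e-05), and in single genes of receptors and mediators. Penk was higher in Gata3-high cells by a log2 fold change of 3.13 ± 0.21, at 1014 ± 260 CPM against 119 ± 27.2 CPM, Il7r, the survival receptor gene for IL-7, by 1.90 ± 0.11, and Rora, a factor of tissue-resident type 2 lymphocytes, by 1.10 ± 0.06. Gzmb was lower by a change of -1.74 ± 0.17, at 796 ± 348 CPM against 2742 ± 47.0 CPM, Ccl4 by -4.16 ± 0.25, and Ccr2, the receptor gene that guides cells to the chemokine CCL2, by -2.78 ± 0.25. Markers of Th1 cells, used for clustering and so not tested, moved with the granzymes and Ccl4. They stood at 3.15 ± 3.71 against 72.7 ± 26.0 CPM for Ifng, 2.97 ± 2.17 against 72.5 ± 14.3 CPM for Il12rb2, 13.2 ± 5.06 against 170 ± 30.2 CPM for Cxcr3 and 137 ± 40.2 against 1808 ± 174 CPM for Ccl5. The Gata3-low sub-clusters, of 323, 158 and 156 cells, were not alike in this. In that order, Ifng stood at 120.7, 12.8 and 44.9 CPM and Il12rb2 at 124.2, 8.2 and 58.2 CPM. Ccl4, Gzmk and Cxcr3 were leading genes of the sub-cluster of 323 cells only. The sub-cluster of 158 cells (median 6425.5 UMIs) was led by S100a4, S100a6 and Ube2c. The Th2 markers Ccr8 and Il4 were higher in Gata3-high cells, at 463 ± 23.7 against 87.1 ± 24.9 CPM and 53.05 ± 11.61 against 4.65 ± 4.17 CPM. Lower there were the cycling markers Ube2c (0.761 ± 1.07 against 13.9 ± 7.37 CPM) and Mki67 (10.96 ± 3.77 against 26.6 ± 8.14 CPM). Top2a, another cycling marker, was about alike (16.4 ± 3.75 against 18.98 ± 5.897 CPM). Of naive or central memory markers S1pr1 was lower (5.55 ± 1.99 against 24.2 ± 6.425 CPM), but Klf2 was not (90.8 ± 16.9 against 71.9 ± 18.7 CPM).

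All 4 granzyme and killing genes were lower in Gata3-high cells (4 over the list alone; camera adjusted p = 5.1e-05, 0.0229 with an estimated correlation), among them Gzmk (-3.81 ± 0.52) and Ctsw (-1.60 ± 0.13). Calls for 7 other lists were lost with an estimated correlation. Suppressive mediators split by member, with 8 of 12 higher, such as Ebi3 (1.57 ± 0.13) and Tgfb1 (0.86 ± 0.07), and 3 lower, such as Lgals1, the galectin-1 gene (-0.73 ± 0.06; the same over the list alone; adjusted p = 0.0312, 0.161 with an estimated correlation). TCR-induced genes were higher, 8 of 11 with 1 lower (the same; 0.000398, 0.210 with an estimated correlation), for example Rel (1.37 ± 0.09), together with 6 of 13 tissue-dissociation stress genes with 1 lower (7 and 1; 0.0248, 0.210 with an estimated correlation, and 0.0548 without library 3), for example Atf3 (1.96 ± 0.18).

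Of 25 T cell transcription factors 11 were higher and 2 lower (13 and 3 over the list alone; adjusted p = 0.00311, 0.0519 with an estimated correlation), and of 83 ribosomal protein genes 69 were higher and 0 lower (74 and 0; 1.4e-20, 0.210 with an estimated correlation). Chemokine and migratory receptors were lower, 5 of 10 with 2 higher (6 and 2; 0.0420, 0.210 with an estimated correlation, and 0.0826 or 0.0505 without library 2 or 4), as were 2 of 9 interferon-gamma GTPases (the same; 0.0139, 0.210 with an estimated correlation, and 0.0527 without library 2).

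The other 10 lists did not pass camera. By fry, cytokine feedback and survival genes and nuclear receptor and AhR genes passed upward (adjusted p = 0.000478 and 0.00764) and glycolysis genes downward (0.00764). Numbers higher and lower were 4 and 4 of 18 cytokine receptors (adjusted p = 0.924), 1 and 1 of 9 co-inhibitory receptors (0.924), 3 and 4 of 10 co-stimulatory receptors (0.751), 2 and 4 of 10 integrins (0.699) and 3 and 4 of 12 effector cytokines (0.879). They were 1 and 4 of 14 glycolysis genes (0.131), 1 and 2 of 17 oxidative phosphorylation genes (0.699), 0 and 0 of 13 genes of cholesterol and fatty acid synthesis (0.924), 6 and 3 of 12 cytokine feedback and survival genes (0.131), and 2 and 0 of 8 nuclear receptor and AhR genes (0.125, though 0.0488 without library 4). Over the lists alone these were the same apart from 5 higher and 5 lower effector cytokines and 2 higher oxidative phosphorylation genes. By library size alone, lower genes numbered 8 for glycolysis, 6 for oxidative phosphorylation, 5 for T cell transcription factors, 4 for interferon-gamma GTPases and 2 for ribosomal proteins, and no other list count moved by over 1.5 times and at least 2 genes. In the cholesterol and co-inhibitory lists the median (0.05 and 0.00) and the direction of camera (down) differed in sign with TMM. By library size alone both medians were negative (-0.05 and -0.10).

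Of 7196 genes tested by edgeR 1062 passed, 562 higher and 500 lower. Adjusted p were 1.2e-11 for Penk, 9.6e-13 for Il7r, 6.5e-14 for Rora, 2.2e-08 for Gzmb, 1.5e-12 for Ccl4 and 4.6e-09 for Ccr2, each in the same direction in 4 of 4 libraries. The sub-clusters were drawn from the same cells that were tested, so these p-values describe differences between sub-clusters and not an independent sorting. By library size alone the median of all genes was -0.10, and 31.1% of calls were higher, against 52.9% with TMM and 53.6% with DESeq2.

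**Figure D4:**
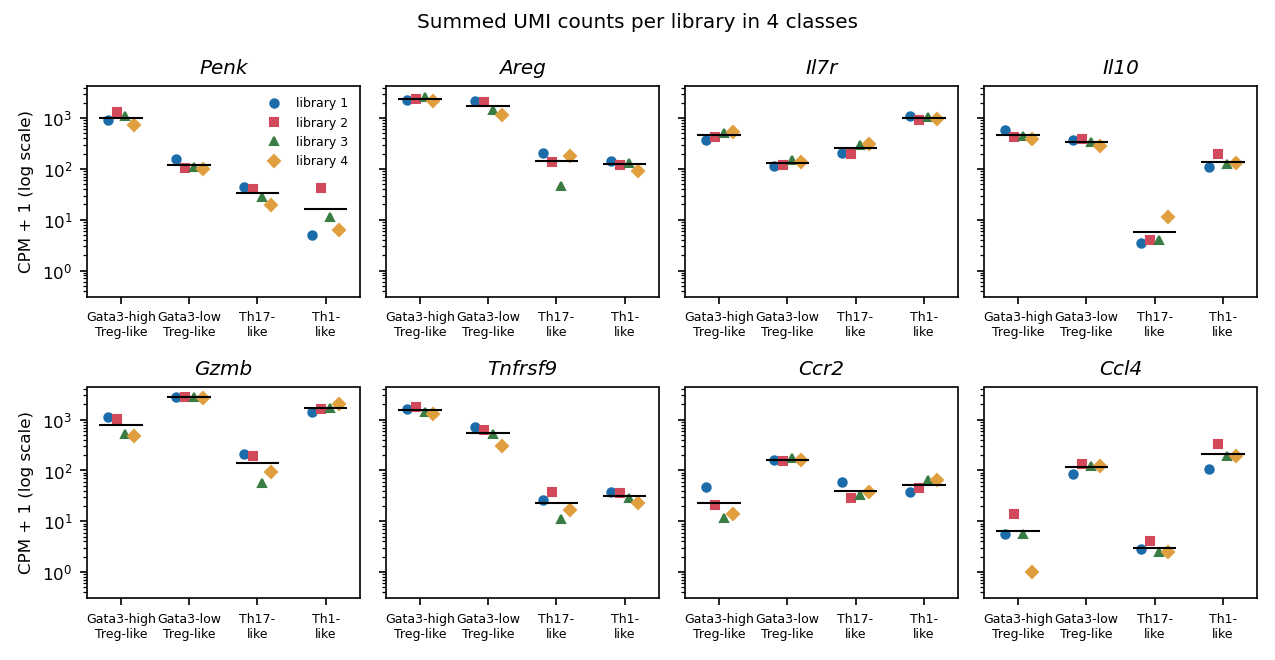
CPM plus 1 on a log scale of Penk, Areg, Il7r, Il10, Gzmb, Tnfrsf9, Ccr2 and Ccl4 in Gata3-high Treg-like, Gata3-low Treg-like, Th17-like and Th1-like cells, with 1 point per library and a line at the mean. Penk averages 1014 CPM in Gata3-high and 119 CPM in Gata3-low cells, Gzmb 796 and 2742 CPM.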

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

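Of the tests below, those of free RNA, of all cytotoxic doublets, of cells with a Trbv UMI and of the share a clone would need, the limit to splits that part every library, and the whole comparison of Gata3-high with Gata3-low cells, were chosen only after the result was seen. The libraries formed 1 group, so the design gave no biological difference between groups to test.

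Th2-like cells were 2.51% of library 4 and 0.666% to 0.764% of the others, and at least 2.44 times the next highest library under every alternative that named such a cluster, which argues against clustering and cell filters. The cluster also held Il17a, at levels that varied by library (see the other observations), and an admixture of cells that express Il17a was not tested. An expanded clone as the whole excess is argued against: it would have to make up 69.5% of the cluster's cells in library 4. There Trbv13-2, the commonest gene, was in 28.6% of cells with a Trbv UMI (upper 95% limit 37.3%), between the 25% and 50% set beforehand, and in library 2, with no raised share, in 31.6%. Innate lymphoid cells, which the CD3 and CD4 sort would remove, could account for part of the share: Trac stood at 0.457 times its level in Th1-like cells of library 4, under the bound of 0.5 set beforehand, with Cd4 at 0.620, Cd3e at 0.749 and Cd3g at 0.821. That explanation cannot be told apart from T cells by the 97.7% of the cluster's cells in library 4 that held a Trbv UMI, as 81.6% of myeloid-like cells and 4 of 8 plasma cell-like cells, shares added once the first value was known, held one too.

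Granzyme and chemokine transcripts were high in Gata3-low Treg-like cells. Doublets with Cd8a-positive cytotoxic cells would bring Cd8a, which reached at most 20.4% of the level their extra Gzmb needs. Gzma, which such doublets would bring as well, reached 123%, 72.9%, 67.8% and 60.4% of the level needed in libraries 1 to 4. These values, and those for Cd8a and Ccl5, count the whole level in Gata3-low cells and not its excess over Gata3-high cells. For Gzma the excess would reach less, as Gata3-high cells held 1915 ± 655 CPM against 3630 ± 595 CPM. Free RNA would bring Th17-like cells as much Gzmb, but the Gata3-low level was at least 13.2 times theirs in each library. Doublets with the cytotoxic cluster poor in Cd8a (56.2 CPM, against 190 CPM in the other) would bring Ccl5, which reached at most 42.5% of the level the extra Gzmb needs, and are argued against as its whole source. For the extra Gzma and Ccl4 they stay open, since Ccl5 reached up to 116% and 101% of the level needed, and down to 42.9% and 61.8% in other libraries.

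Other splits of the class sums were counted. The share set beforehand counted all of them (32, 35 and 35), but both sums of a library belong together, so the real split was compared with the splits that part every library. These are 8 in each comparison, too few for a share under 0.05. The classes were also made by clustering these same cells, so few calls in splits that mix them were likely beforehand. The counts therefore do not decide whether chance played a part. The real one alone, 1 of 8, gave as many genes for Treg-like against other cells (3715, highest other 0), for Th17-like against Th1-like cells (2065, highest other 1) and for Gata3-high against Gata3-low cells (1062, highest other 0). The remaining splits parted fewer libraries and gave at most 0, 4 and 2 genes, with 3 not fitted in the first comparison.

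Of 90 groups of 4 library values, 8 held a library far from the others, where chance gives about 1 in 20, or 4.5. Tfh-like cells were 2.26% of library 1 (others 1.03% to 1.20%), and cytotoxic cells 16.6% of library 4 (others 11.5% to 12.3%). Between Treg-like and other cells Itih5 had a log2 fold change of 3.51 in library 4 (others 4.02 to 4.08) and Xcl1 of -5.82 in library 3 (others -3.30 to -2.92). Between Th17-like and Th1-like cells Tnfsf8 stood at 0.97 in library 2 (others 1.83 to 1.93) and Ccl4 at -4.96 in library 1 (others -6.16 to -5.99). Between Gata3-high and Gata3-low cells Slamf6 stood at -2.52 in library 2 (others -1.21 to -1.05).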

How the results depend on the processing

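Leaving out the mixed Treg-like sub-cluster, leaving out the innate-like, Cd8a-led and Fabp6-led clusters, and every value for Gata3-high against Gata3-low cells were chosen only after the result was seen. Across 17 and 16 alternatives, the count for Treg-like against other cells (2594 to 4092, and 3696 without those 3 clusters) and for Gata3-high against Gata3-low cells (743 to 1281) stayed within 1.5 times its value, as did the Treg-like share over all that were run. Named genes that passed in every setting were 77 of 80 for Treg-like against other cells, 61 of 76 for Th17-like against Th1-like cells and 63 of 70 for Gata3-high against Gata3-low cells. Depth limits what can be detected, with 107 to 239 Th17-like cells per library.

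UMI gates gave 892 genes for Th17-like against Th1-like cells, against 2065, and there Tigit (0.016) and Tnfrsf1b (0.021) stood near 0 and did not pass (adjusted p = 0.936 and 0.902), while Nr3c1 (0.176) passed in the other direction (adjusted p = 0.0424). The cause was not tested.

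Th17-like cells made up 6.79% at a mitochondrial share of at most 5%, 4.97% and 5.22% at lower and higher resolution and 14.2% with UMI gates, Th1-like cells 18.7%, 17.7% with library-centred clustering and 32.8% with UMI gates. Cytotoxic cells made up 6.76% without doublet removal and 8.46% at lower resolution, unnamed cells 51.6% without doublet removal, 42.5% at a mitochondrial share of at most 5% and 43.99% at higher resolution. The innate-like share had no value at higher resolution or with library-centred clustering. Detection of Foxp3, Ikzf2 and Gata3 was 71.2%, 92.7% and 66.0% without thinning and 19.3%, 53.3% and 27.5% at 2 UMIs or more, which the depth and the threshold set by construction. The cause of the other moves was not tested.

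With an estimated correlation, lists that passed camera were 0 for Treg-like against other cells, 6 for Th17-like against Th1-like cells and 1 for Gata3-high against Gata3-low cells. For Treg-like against other cells the estimate lay under the preset 0.01 for suppressive mediators (-0.0584) and co-inhibitory receptors (-0.0792). It lay above for T cell transcription factors (0.023). A higher correlation therefore does not explain the lost calls for suppressive mediators and co-inhibitory receptors.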

Other observations

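No test in this part was run beyond levels and shares in each class, and which genes to list was chosen only after the result was seen. Th2-like cells held 193 ± 101 CPM of Il13 and 87.6 ± 77.8 CPM of Il5, cytokines of type 2 immunity that act on epithelium and eosinophils, with 612 ± 217 CPM of Gata3 and 409 ± 152 CPM of Areg (mean and SD, n = 4 libraries). The same class also held Il17a, at 798 ± 655 CPM, between 19.8 and 1603 CPM in the 4 libraries, against 1037 ± 482 CPM in Th17-like cells. Cytotoxic cells formed 2 clusters of 2074 and 735 cells, which held Gzma at 5802 ± 1199 and 8874 ± 539 CPM, Ccl5 at 12270 ± 2722 and 13630 ± 1508 CPM, and Cd4 at 410 ± 20.4 and 427 ± 59.5 CPM, against 480 ± 32.0 CPM in Th1-like cells.

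Treg-like cells held Epcam, the gene of an epithelial adhesion molecule, at 204 ± 22.7 CPM in Gata3-high and 38.3 ± 7.14 CPM in Gata3-low cells, against 6.98 ± 1.22 CPM in cytotoxic and 11.4 ± 1.70 CPM in Th1-like cells. Il1rl1, the receptor gene for the alarmin IL-33, stood at 287 ± 27.2 CPM in Gata3-high, 31.0 ± 12.4 CPM in Gata3-low and 85.6 ± 56.5 CPM in Th2-like cells. Tfh-like cells held Areg at 491 ± 157 CPM and Penk at 137 ± 45.4 CPM, against 8.90 ± 10.3 and 2.51 ± 5.02 CPM in naive or central memory-like cells. Tfh-like cells also held transcripts of Treg genes: after thinning to 2000 UMIs, 10.8% ± 4.66 of them held a Foxp3 UMI and 49.4% ± 3.99 an Ikzf2 UMI, against 0.657% ± 0.0818 and 18.7% ± 1.67 of all αβ cells outside the Treg-like class, at median depths of 4496 and 3753 UMIs before thinning.

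Clusters without a name were led by Il2, Dtx1, Il7r and Cd40lg (5208 cells, from 15.3% of library 1 to 30.3% of library 4), by Ramp3, Nr4a3 and Tnfsf11 (3870 cells, from 11.2% of library 4 to 26.1% of library 1), by Ccl1, Crtam and Xcl1 (449 cells) and by Eomes and Gzmk (399 cells). A further cluster of 254 cells with a median of 1531 UMIs was led by Fabp6 and Apoa1, genes of absorptive epithelium.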
